A study of Mus musculus with 6 samples.

How the data were processed

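Gene expression was measured by sequencing RNA from mouse kidney in 6 libraries. Per the labels, 3 libraries came from mice given the empty plasmid pcDNA3 (control) and 3 from mice given a plasmid for Wnt1, a secreted ligand of the Wnt/beta-catenin pathway. Replicates carry the numbers 1 to 3 in the order of the records, so a number names a library and pairs nothing. The labels name 1 batch for all libraries, and give no injury procedure, sex, age or time after plasmid delivery. Nothing in them says that each library came from a separate animal, so p-values measure only the spread between these samples, which may be technical.

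Per the labels' protocols, RNA was extracted with Trizol, messenger RNA was enriched on oligo(dT) beads, fragmented and reverse transcribed with the NEBNext Ultra kit, and sequenced on an Illumina NovaSeq instrument. Per the submitters' processing notes, fastp 0.18.0, Bowtie2 2.2.8, HISAT2, StringTie 1.3.1 and RSEM were used with the mm10 build. The role of each tool, the annotation release, and whether strand was used in counting are not given in the sources used here. The authors deposited an expected count, an estimated number of reads that need not be whole, for each gene and library. They also deposited an FPKM value for each gene and library, a fragment count scaled by transcript length and library total with no factor for composition. The table held 22183 genes with Ensembl identifiers, symbols and KEGG pathway terms, and no value column of another sample. Of the expected counts, 9.02% differed from a whole number by more than 1e-06, and all were rounded. Gene identifiers were matched to the GENCODE M21 annotation of GRCm38, the assembly that mm10 names; 22128 matched, 98.2% of them as protein coding, and 55 did not match. Coordinates, transcript GC content and transcript length come from that annotation.

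Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr were kept, libraries were scaled by TMM factors, and Wnt1 was compared with control by the robust quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment over 14432 tested genes. A gene was called at an adjusted p under 0.05. Log2 fold changes are Wnt1 over control, each followed after ± by a standard error. That error was derived from the unshrunken coefficient and the quasi-likelihood F statistic, so it holds no information independent of the p-value. Levels are counts scaled by library total and TMM factor (CPM), as mean ± SD of 3 libraries. A gene with no count in a group was given a lower bound for its fold, taken at 3 counts per library, and one with 1 to 3 counts in a group a ratio with an exact 95% interval for counting error only. The protocols mention no molecular identifiers, so intervals and floors cover counting error only.

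Before the data were examined, 52 gene lists were fixed: pathways and processes, kidney and immune cell types, other tissues, and technical sets. The 50 lists with at least 3 tested members were tested with camera in limma 3.58.1, two-sided, with a preset correlation of 0.01 and adjustment over the lists. Camera with an estimated correlation and fry were alternatives. With an estimated correlation, camera takes its degrees of freedom from the 6 libraries rather than from the genes. That alone raises its p-values, whatever the correlation. Fry asks whether a list's genes move one way on balance, without comparing them with other genes. Named genes were also chosen by a rule set beforehand. It took a fixed set of genes whatever their values, of which Wnt1, Atf3, Ctnnb1, Axin2, Pink1, Havcr1 and Lcn2 are given. It took the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap, whose mean FPKM was at least 1 in the higher group, and whose symbol was not that of a predicted gene, clone or pseudogene. From each list it took up to 4 called members with the smallest p; had no gene passed, the 5 smallest unadjusted p in each direction would have been named. Some genes, among them some that the rule took, are not reported here and are not counted among those followed across settings.

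The alternatives were DESeq2 1.42.0, median-ratio and upper-quartile factors, no filter and a stricter filter (CPM of at least 1 in all 3 libraries of a group), limma on log2(FPKM + 1) and log2(FPKM + 0.1) with an FPKM of at least 1 in 3 libraries or with no filter, voom with quality weights, 1 surrogate variable from sva 3.50.0, named symbols only, and leaving out each library. For lists they were the estimated correlation, fry, the FPKM scale, leaving out each library, and leaving out the called member with the largest change. Chosen after seeing the data were leaving out control replicate 3 and Wnt1 replicate 3 together, a covariate for these libraries (also with the estimated correlation for lists), an offset for GC content, and scaling by library totals. The KEGG terms in the table were tested with camera, also after seeing the data, where they held 10 to 300 tested genes.

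The count test was tested on simulated counts for this comparison with 13724 genes passing the filter. It recovered 49% of 100 genes seeded at a log2 change of 1 and 86% of 100 seeded at 2, and 5 of 141 calls were false. A simulated list of 30 genes raised by 0.5 was called, and 2 of 100 unchanged lists had p under 0.05. Genes were drawn independently, so the simulation does not test camera on lists with correlated members. In the data the estimated correlation was, for example, 0.879 for nuclear OXPHOS subunits. The simulation also changed only a small part of the genes and set no composition difference between the groups, unlike the data. Within groups, chi-square per degree of freedom between libraries lay between 16.1 and 95.4 for genes with at least 10 counts, so no library repeated another.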

Results

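Kidney messenger RNA was profiled in mice that received either an empty plasmid (pcDNA3) or a plasmid for Wnt1, with 3 libraries in each group. The series title names Wnt/beta-catenin/ATF3 signalling, mitophagy and the passage from acute kidney injury to chronic kidney disease as the subject. The only comparison the labels define asks which kidney transcripts differed between the Wnt1 plasmid and the empty vector. Expected counts summed to 24753193, 26072435 and 25824543 in control replicates 1, 2 and 3. They summed to 27218085, 23656312 and 23585020 in Wnt1 replicates 1, 2 and 3.

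Wnt1 itself (ENSMUSG00000022997; GRCm38 chromosome 15, 98789857 to 98793837) had 0 reads in each control library and 0, 1 and 0 reads in Wnt1 replicates 1, 2 and 3. An exact permutation test, two-sided, gave p = 1, and the smallest p that 3 against 3 libraries allow is 0.1. At 3 counts, the limit that a count of 0 allows corresponded to between 0.0951 and 0.138 CPM per library, so lower levels are not excluded. The gene on the plasmid therefore did not check the labels. The first principal component held 78.0% of the variance and parted all control libraries from all Wnt1 libraries. The second held 14.7% and set control replicate 3 (score -29.0) and Wnt1 replicate 3 (-50.1) apart from the other 4 libraries (16.2 to 22.1).

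**Figure D1:**
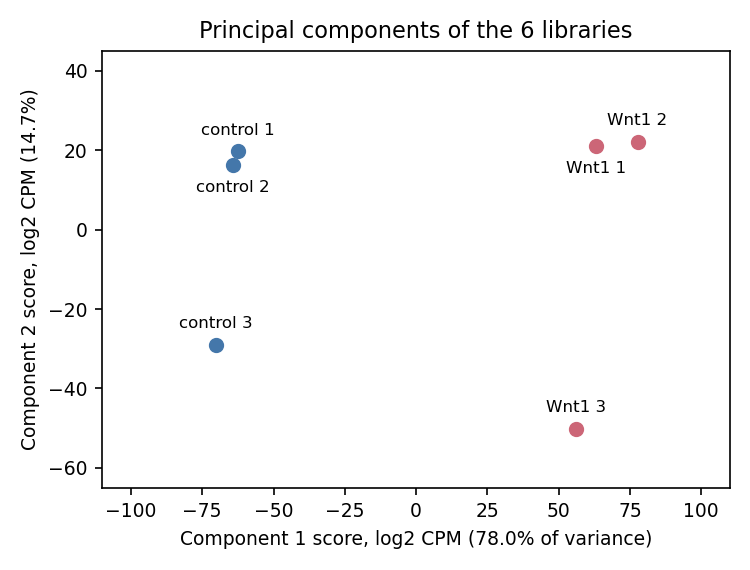
Scores of the 6 libraries on the first and second principal components of log2 CPM, 1 point per library, blue for control and red for Wnt1. Component 1 (78.0% of variance) parts the groups, and component 2 (14.7%) sets control replicate 3 and Wnt1 replicate 3 below the others.

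Transcripts used as markers of tubular injury were far higher with the Wnt1 plasmid, and markers of the proximal tubule were lower. Havcr1, which encodes a kidney injury molecule of the tubule, went from 2.59 ± 0.809 to 447 ± 105 CPM, a log2 fold change of 7.43 ± 0.31 (edgeR adjusted p = 1.66e-05). Lcn2, encoding the injury-released lipocalin NGAL, went from 4.93 ± 0.503 to 369 ± 92.1 CPM (6.22 ± 0.24; adjusted p = 1.45e-05). Atf3, a stress-induced transcription factor, rose by 2.38 ± 0.39 (adjusted p = 0.00226), from 2.48 ± 1.19 to 13 ± 3.43 CPM. Pink1, the kinase that starts mitophagy, fell, with a log2 fold change of -1.69 ± 0.19 (adjusted p = 0.000327) and levels of 498 ± 65.3 and 154 ± 33.4 CPM. In all, 5936 of 14432 tested genes were called by edgeR, 3239 higher and 2697 lower with Wnt1, and 3292 of them changed at least 2-fold (2214 higher and 1078 lower). The groups did not overlap for 53.5% of tested genes, against 10% by chance.

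The scaling of the libraries shifted all genes together. The 10 most abundant genes took 15.4% to 15.8% of counts in controls and 8.48% to 10.9% with Wnt1, and TMM factors were 0.848 to 0.879 against 1.12 to 1.19. The median log2 fold change of all tested genes was 0.05 with TMM and 0.47 with library totals, and the calls then split into 6348 higher and 1288 lower. On the authors' FPKM scale limma gave 5144 higher and 1238 lower. With control replicate 3 and Wnt1 replicate 3 both left out, a choice made after seeing the data, 9096 genes were called, 4664 higher and 4432 lower. Changes are given on the TMM scale. For lists, further counts are given under library totals, with a GC offset (also a choice made after seeing the data) or without both libraries numbered 3, where the larger of the 2 counts moved by over 1.5 times or the balance turned.

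Of the remaining genes named beforehand, Axin2, a direct target and feedback inhibitor of Wnt/beta-catenin signalling, rose by 1.57 ± 0.41 (adjusted p = 0.0169). Its levels were 3.5 ± 0.249 CPM in control and 10.5 ± 6.41 CPM with Wnt1, where replicate 3 stood at 17.8 CPM and replicates 1 and 2 at 6.24 and 7.29. Without Wnt1 replicate 3 the log2 fold change was 0.95, and without control replicate 1 or 2 the adjusted p was 0.0503 or 0.0535 at log2 fold changes of 1.58 or 1.57 (adjusted p over the alternatives 4.99e-05 to 0.0535). Ctnnb1, which encodes beta-catenin, was measured at 628 ± 19.5 and 647 ± 50.2 CPM, with a log2 fold change of 0.04 ± 0.12 (adjusted p = 0.799). With library totals it was called higher at 0.46 (adjusted p = 0.00746; range over the alternatives 0.00692 to 0.96), about the shift of all genes under that scaling. In GRCm38, Havcr1 lies on chromosome 11, 46735080 to 46779578, Lcn2 on chromosome 2, 32384633 to 32388252, Atf3 on chromosome 1, 191170296 to 191218039, and Pink1 on chromosome 4, 138313409 to 138326307. Axin2 lies on chromosome 11, 108920349 to 108950783 and Ctnnb1 on chromosome 9, 120929216 to 120960507.

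**Figure D2:**
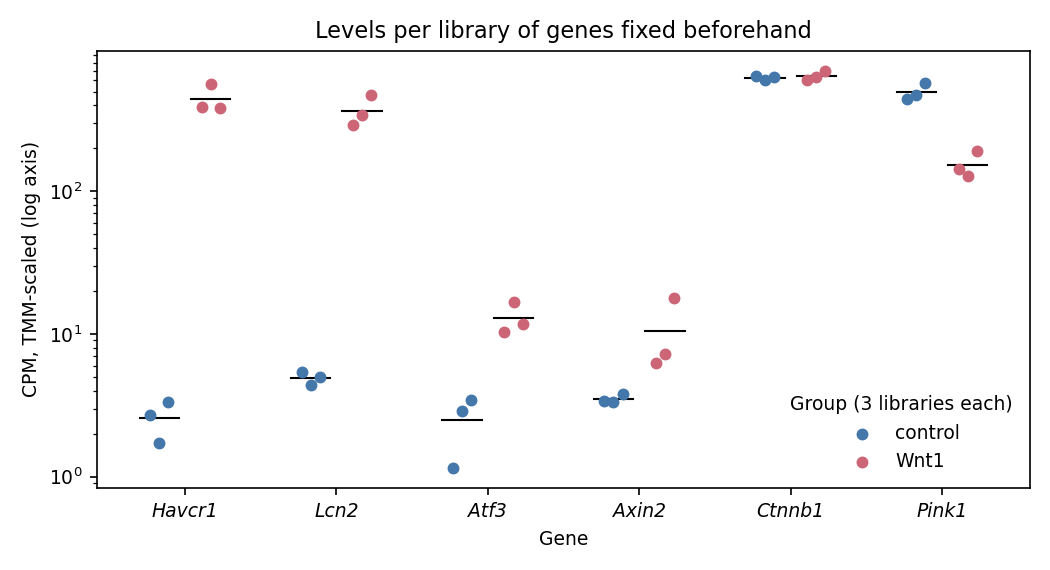
TMM-scaled CPM on a log axis of 6 genes named before the data were examined, with 1 point per library (blue control, red Wnt1, 3 each) and a line at each group mean. Havcr1 lies between 1.73 and 3.33 CPM in control and between 384 and 568 CPM with Wnt1, while the groups overlap for Ctnnb1.

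The largest fitted rises by the naming rule included epithelial, secretory and chemoattractant genes that were near 0 in control kidneys. Sprr2f, a small proline-rich protein of stressed epithelia, had no control count and was at least 73.4-fold higher with Wnt1. Vgf, a neuropeptide precursor, was at least 28.2-fold higher, Serpina6, corticosteroid-binding globulin, at least 19.3-fold, Sftpd, surfactant protein D, at least 12.7-fold, and Saa3, an acute-phase protein, at least 7.45-fold. Few control counts left wide ratios for Arhgap36 (545, 95% interval 150.5 to 4502, from 2 control counts), Cxcl17 (469.7, 84 to 18582, from 1), Cxcl5 (404, 72.1 to 15971, from 1) and Il36a (258, 71.1 to 2134, from 2). Mmp7, the matrix protease matrilysin, went from 0.121 ± 0.0964 to 41.4 ± 5.14 CPM (8.36 ± 0.35; 9.23 without control replicate 1). Fitted folds over no or few control counts are uncertain, so the rank of these genes above others, such as Havcr1, is not established.

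The largest fitted falls held transporters, catabolic enzymes and markers of distal segments. Egf, made in the thick ascending limb and distal tubule, fell from 2219 ± 147 to 77.3 ± 39.7 CPM (-4.84 ± 0.43). Slc22a7, an organic anion transporter, had a log2 fold change of -5.67 ± 0.67 (-6.61 without Wnt1 replicate 3), Slco1a1, another organic anion transporter, -4.82 ± 0.18, and Hpd, an enzyme of tyrosine breakdown, -5.53 ± 0.27. Cyp2d12, a cytochrome P450 of a multi-copy family, had a log2 fold change of -6.12 ± 0.32, Hrg, histidine-rich glycoprotein, -5.77 ± 0.62 (-7.32 without Wnt1 replicate 3), and Pvalb, a calcium-binding protein of the distal convoluted tubule, -4.81 ± 0.54 (-5.69 without Wnt1 replicate 1). Kcnt1 (-5.63 ± 0.37), Pde6a (-5.36 ± 0.31) and Fcamr (-4.94 ± 0.29) completed the 10. Adjusted p of these 20 genes lay between 1.26e-05 and 0.00205. Genes of families with near-identical copies, such as Cyp2d12, Sprr2f and Saa3, could share reads, and how such reads were divided is not given in the sources used here.

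Across the fixed lists, camera with the preset correlation called 33 of 50, 18 higher and 15 lower. With an estimated correlation camera called 0, with a smallest adjusted p of 0.109 and 12 lists at an unadjusted p under 0.05, and fry called 39. A lost call there need not come from members moving together, because fewer degrees of freedom alone raise the p-values. The estimated correlation was -0.0021 for Wnt/beta-catenin targets, -0.020 for renin-angiotensin genes and -0.022 for regulated cell death genes. Each of these lies under the preset 0.01, yet for Wnt/beta-catenin targets the unadjusted camera p went from 0.000198 to 0.0143. The 0 calls therefore do not decide whether list calls come from members moving together. Fry kept the 33 calls and also called lists that camera did not. Higher by fry were Wnt pathway components (fry adjusted p = 0.0087), the integrated stress response (0.0346) and smooth muscle (0.0245). Lower by fry were autophagy and lysosome (0.0353), hypoxia response (0.0405) and circadian clock genes (0.0249). Other splits of the same 6 libraries gave between 14 and 35 called lists by camera with the preset correlation.

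**Figure D3:**
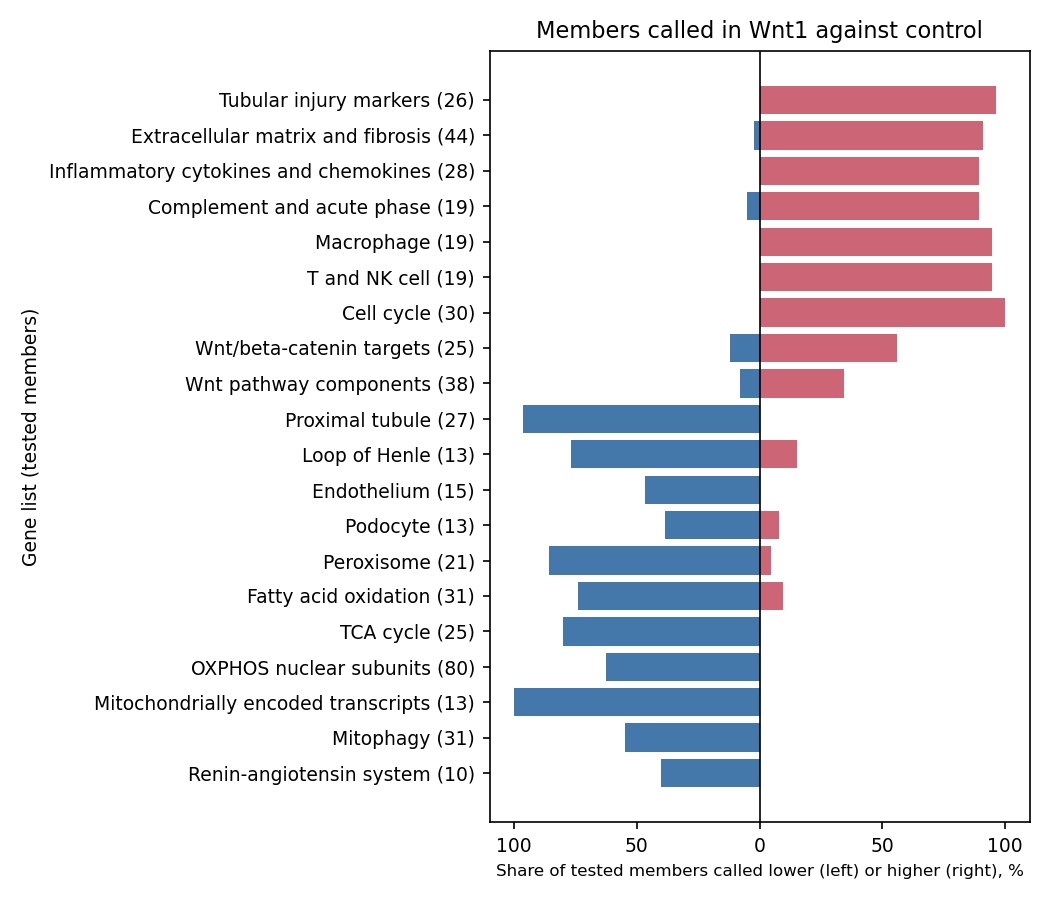
Share of the tested members of selected lists called higher (red, right) or lower (blue, left) with Wnt1 by edgeR, in percent, with the number of tested members in brackets. All 30 cell cycle members are called higher and all 13 mitochondrially encoded transcripts lower (8 lower with library totals).

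Tubular injury markers were higher almost throughout (25 higher and 0 lower of 26 tested, the same adjusted over the list alone; median log2 fold change 2.64; camera adjusted p = 1.53e-33, and adjusted p = 0.109 with an estimated correlation). Besides Havcr1 and Lcn2 they included Krt20 (6.76 ± 0.36) and the protease inhibitor Timp1 (6.45 ± 0.22). Of the 26 tested members, 4 also stand in other lists. Markers of macrophages (median 2.99), neutrophils (4.04) and fibroblasts and mural cells (1.48) rose in the same libraries. Which cells the injury transcripts come from is therefore not known. Extracellular matrix and fibrosis genes followed (40 higher and 1 lower of 44 tested, the same adjusted over the list alone; median 1.89; camera adjusted p = 2.69e-22, and 0.198 as the adjusted p with an estimated correlation), with Col12a1 (4.25 ± 0.23), the latent TGF-beta binding protein Ltbp2 (5.14 ± 0.32) and the membrane protease Mmp14 (2.70 ± 0.16). TGF-beta targets rose in part (9 higher and 0 lower of 17 tested, 10 and 0 adjusted over the list alone; camera adjusted p = 0.000431, and adjusted p = 0.27 with an estimated correlation; 14 higher with library totals), among them Tgfbi (2.14 ± 0.17). Fibroblast and mural cell markers, 14 of whose 18 members also stand in other lists, moved with them (13 higher and 1 lower of 18 tested, 13 and 2 adjusted over the list alone; camera adjusted p = 1.29e-06, and adjusted p = 0.235 with an estimated correlation). Col3a1 rose by 2.86 ± 0.24 and Tagln by 1.99 ± 0.18.

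Immune transcripts were higher across every leukocyte list. Macrophage markers gave 18 higher and 0 lower of 19 tested, 19 and 0 adjusted over the list alone (median 2.99; camera adjusted p = 6e-33, and adjusted p = 0.109 with an estimated correlation). They included lysozyme, Lyz2, at 44.8 ± 7.14 and 879 ± 64.4 CPM (4.30 ± 0.17), and the integrin Itgam (4.69 ± 0.24). Neutrophil markers gave 7 higher and 0 lower of 8 tested, the same adjusted over the list alone (camera adjusted p = 4.06e-08, and adjusted p = 0.109 with an estimated correlation). They included S100a9 (4.87 ± 0.56) and the G-CSF receptor Csf3r (3.07 ± 0.25). Only 8 of the 13 neutrophil markers named passed the filter, and 2 of the 8 also stand in other lists. T and NK cell markers gave 18 higher and 0 lower of 19 tested, the same adjusted over the list alone (camera adjusted p = 3.37e-05, and adjusted p = 0.27 with an estimated correlation). They included Cd4 (1.97 ± 0.22). B and plasma cell markers gave 7 higher and 0 lower of 8 tested, the same adjusted over the list alone (camera adjusted p = 0.00271, and adjusted p = 0.198 with an estimated correlation). They included Cd22 (3.24 ± 0.30) and Ighm (2.10 ± 0.26). Of the 15 B and plasma cell markers named, 8 passed the filter, so members low in both groups are not counted.

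Inflammatory mediators moved in the same direction as the leukocyte markers. Cytokines and chemokines gave 25 higher and 0 lower of 28 tested, 26 and 1 adjusted over the list alone (camera adjusted p = 4.86e-19, and adjusted p = 0.109 with an estimated correlation). They included Ccl2 (4.21 ± 0.25), the monocyte chemoattractant. Complement and acute phase genes gave 17 higher and 1 lower of 19 tested, 17 and 2 adjusted over the list alone (camera adjusted p = 2.49e-16, and adjusted p = 0.167 with an estimated correlation). They included C3, from 27.1 ± 1.73 to 1742 ± 163 CPM, and Serpina3n (7.63 ± 0.31). Interferon-stimulated genes gave 29 higher and 0 lower of 37 tested, 32 and 0 adjusted over the list alone (camera adjusted p = 1.62e-08, and adjusted p = 0.167 with an estimated correlation). They included Oasl1 (1.94 ± 0.18) and Isg20 (2.08 ± 0.20). Antigen presentation genes gave 18 higher and 0 lower of 21 tested, 19 and 0 adjusted over the list alone (camera adjusted p = 1e-10, and adjusted p = 0.27 with an estimated correlation). They included B2m (1.61 ± 0.12) and the MHC class II activator Ciita (2.08 ± 0.16).

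Targets of Wnt/beta-catenin signalling were mixed (14 higher and 3 lower of 25 tested, the same adjusted over the list alone; median 1.38; camera adjusted p = 0.000431, and adjusted p = 0.119 with an estimated correlation). The feedback inhibitors Nkd2 (4.11 ± 0.19) and Nkd1 (2.01 ± 0.20) and the adhesion receptor Cd44 (4.51 ± 0.36) rose. Camera on log2(FPKM + 1) gave an adjusted p of 0.0503 for this list, with a mean log2 change relative to all tested genes of 0.88 against 1.23 (adjusted p over the alternatives 0.000181 to 0.312). Wnt pathway components were not called as a list (camera adjusted p = 0.0845), with 13 higher and 3 lower of 38 tested, the same adjusted over the list alone, and 24 higher with library totals. The ligands Wnt4 (3.35 ± 0.22), Wnt7a (4.18 ± 0.44, and 4.84 without control replicate 3), Wnt10a (3.36 ± 0.58, and 4.0 without it) and Wnt2 (2.05 ± 0.30) were among those that rose. Over the alternatives their log2 fold changes went as low as 2.60 for Wnt4, 0.89 for Wnt7a, 1.92 for Wnt10a and 1.08 for Wnt2. Wnt7a was tested in only 19 of 21 alternatives, so the size of its rise is uncertain. Renin-angiotensin genes gave 0 higher and 4 lower of 10 tested, 0 and 6 adjusted over the list alone, and 7 lower both with a GC offset and without both libraries numbered 3 (camera adjusted p = 0.0127, and adjusted p = 0.198 with an estimated correlation). Angiotensin-converting enzyme, Ace, had a log2 fold change of -2.26 ± 0.21 and the angiotensin receptor gene Agtr1a -0.96 ± 0.13; without Ace, the list's member with the largest change, the camera adjusted p was 0.0709 and the mean log2 change relative to all tested genes -0.84, against -1.0 (adjusted p over the alternatives 0.00216 to 0.298).

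Mitophagy genes were called in 1 direction on the TMM scale, with 0 higher and 17 lower of 31 tested, 0 and 18 adjusted over the list alone, but library totals left 4 lower and made 2 higher (median -0.48 against -0.06). The list's camera adjusted p was 0.000131, and the adjusted p with an estimated correlation was 0.354. Beside Pink1, the ATG8-family gene Gabarapl1 (-1.80 ± 0.16), the outer-membrane receptor Bnip3 (-0.83 ± 0.13) and Nipsnap1 (-1.13 ± 0.15) fell. Mitochondrial biogenesis and dynamics genes gave 0 higher and 9 lower of 21 tested, 0 and 10 adjusted over the list alone (camera adjusted p = 0.0145, and adjusted p = 0.226 with an estimated correlation). They had 1 lower with library totals, 15 lower with a GC offset, and 15 lower and 2 higher without both libraries numbered 3. Autophagy and lysosome genes were not called as a list (camera adjusted p = 0.138), with 4 higher and 11 lower of 32 tested, the same adjusted over the list alone, against 11 higher and 5 lower with library totals, and 5 higher and 17 lower without both libraries numbered 3. The lysosomal sialidase Neu1 fell (-1.47 ± 0.14) and cathepsin S, Ctss, which macrophages also make, rose (3.51 ± 0.16). Without Ctss the list was called lower (camera adjusted p = 0.0283, range over the alternatives 0.0283 to 0.635). In the same libraries, markers of the proximal tubule, which is rich in mitochondria, had a median of -1.83 and macrophage markers one of 2.99.

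Transcripts for oxidative metabolism were lower on the TMM scale. Mitochondrially encoded transcripts gave 0 higher and 13 lower of 13 tested, the same adjusted over the list alone (8 lower with library totals; camera adjusted p = 3.06e-06, and adjusted p = 0.354 with an estimated correlation). They took 11.3% to 12.2% of counts in control libraries and 5.04% to 8.04% with Wnt1. Nuclear OXPHOS subunits gave 0 higher and 50 lower of 80 tested, 0 and 56 adjusted over the list alone, and 15 lower with library totals (camera adjusted p = 3.75e-09, and adjusted p = 0.543 with an estimated correlation). TCA cycle genes gave 0 higher and 20 lower of 25 tested, 0 and 21 adjusted over the list alone (camera adjusted p = 1.14e-08, and adjusted p = 0.27 with an estimated correlation). They included pyruvate carboxylase, Pcx (-2.26 ± 0.20), and Sdha (-1.14 ± 0.14). Fatty acid oxidation genes gave 3 higher and 23 lower of 31 tested, 3 and 24 adjusted over the list alone (15 lower with library totals; camera adjusted p = 1.85e-08, and adjusted p = 0.27 with an estimated correlation). They included Acsm3 (-3.16 ± 0.23) and Acsm2, both acyl-CoA synthetases, the latter going from 4686 ± 253 to 823 ± 87.6 CPM. Peroxisome genes gave 1 higher and 18 lower of 21 tested, 1 and 20 adjusted over the list alone (camera adjusted p = 1.51e-10, and adjusted p = 0.198 with an estimated correlation). They included Acox2 (-2.03 ± 0.14) and catalase, Cat (-1.42 ± 0.13). In the same libraries proximal tubule markers had a median of -1.83 (26 of 27 lower), so the falls in metabolic lists are not separated from theirs.

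Markers of the proximal tubule fell almost throughout (0 higher and 26 lower of 27 tested, 0 and 27 adjusted over the list alone; camera adjusted p = 8.9e-25, and adjusted p = 0.109 with an estimated correlation). The phosphate transporter Slc34a1 went from 6209 ± 238 to 1150 ± 309 CPM (-2.43 ± 0.22), and Miox and Slc7a13 had log2 fold changes of -2.73 ± 0.21 and -3.52 ± 0.27. Loop of Henle markers gave 2 higher and 10 lower of 13 tested, 3 and 10 adjusted over the list alone (camera adjusted p = 0.00351, 0.0581 without both libraries numbered 3, where the mean log2 change relative to all tested genes was -1.40 against -1.30, adjusted p over the alternatives 6.9e-05 to 0.62, and adjusted p = 0.385 with an estimated correlation), with the claudin Cldn4 rising (2.29 ± 0.17) against Egf. Intercalated cell markers gave 0 higher and 8 lower of 12 tested, the same adjusted over the list alone, and 4 lower with library totals (camera adjusted p = 0.0011, and adjusted p = 0.354 with an estimated correlation). Distal convoluted tubule markers gave 1 higher and 5 lower of 10 tested, the same adjusted over the list alone, and 3 lower with library totals (camera adjusted p = 0.0288, and adjusted p = 0.497 with an estimated correlation). That call was lost without control replicate 1 (adjusted p = 0.058), without Wnt1 replicate 3 (0.159) and without its member with the largest change (0.109). It was also lost with a covariate for both libraries numbered 3 (0.0989) and without them (0.205), with a range over the alternatives of 0.00122 to 0.62. The list's mean log2 change relative to all tested genes was -1.08, and in these settings, in the same order, -1.02, -0.98, -0.64, -1.07 and -1.04.

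Endothelial and podocyte markers were lower in part on the TMM scale. Endothelial markers gave 0 higher and 7 lower of 15 tested, 0 and 10 adjusted over the list alone, against 1 lower with library totals, 12 with a GC offset and 14 without both libraries numbered 3 (camera adjusted p = 0.00594, and adjusted p = 0.385 with an estimated correlation); the VEGF receptor gene Kdr fell from 113 ± 5.8 to 56.3 ± 3.95 CPM. Podocyte markers (1 higher and 5 lower of 13 tested, the same adjusted over the list alone; camera adjusted p = 0.346) were 6 higher and 2 lower with library totals. Collecting duct principal cell markers gave 0 higher and 1 lower of 11 tested, the same adjusted over the list alone (camera adjusted p = 0.334; 0.0437 without Wnt1 replicate 3, range over the alternatives 0.032 to 0.846), the called gene being the water channel Aqp3 (-1.35 ± 0.22). Library totals made 3 of them higher, a GC offset made 4 lower, and leaving out both libraries numbered 3 made 7 lower. Androgen-dependent kidney genes gave 2 higher and 8 lower of 12 tested, 2 and 9 adjusted over the list alone (camera adjusted p = 1.3e-05, and adjusted p = 0.198 with an estimated correlation), with Cyp7b1 at -4.08 ± 0.30 and Aoc1 rising by 4.82 ± 0.17. Their median was -1.67, beside -1.83 for proximal tubule markers, and 2 of the 12 stand in other lists. Their fall is not separated from that of the proximal tubule markers. The smooth muscle list, 5 of whose 10 members stand in other lists, was not called (4 higher and 2 lower of 10 tested, the same adjusted over the list alone; camera adjusted p = 0.15). Nor were urothelium (3 higher and 0 lower of 10 tested, the same adjusted over the list alone; camera adjusted p = 0.529) and liver (3 higher and 4 lower of 10 tested, the same adjusted over the list alone; camera adjusted p = 0.606). Adipocyte (1 higher and 1 lower of 5 tested, the same adjusted over the list alone; camera adjusted p = 0.789; 2 lower without both libraries numbered 3) and red blood cell lists (0 higher and 1 lower of 8 tested, the same adjusted over the list alone; camera adjusted p = 0.529) were not called either, and their tests pointed lower although their medians were 0.06 and 0.03. Adrenal and skeletal muscle lists had fewer than 3 tested members.

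Cell cycle genes were higher in libraries where leukocyte and fibroblast markers were higher too, with medians of 2.99 for macrophages, 1.88 for T and NK cells, 2.67 for B and plasma cells and 1.48 for fibroblasts and mural cells, so which cells they come from is not known. All cell cycle members rose (30 higher and 0 lower of 30 tested, the same adjusted over the list alone; camera adjusted p = 3.85e-09, and adjusted p = 0.27 with an estimated correlation), among them Cdk1 (2.08 ± 0.23) and Rrm2 (1.88 ± 0.19). The p53 and senescence list gave 8 higher and 1 lower of 17 tested, 9 and 1 adjusted over the list alone, and 13 higher with library totals (camera adjusted p = 0.0204, and adjusted p = 0.27 with an estimated correlation), with the cell cycle inhibitor Cdkn1a at 2.30 ± 0.16. Regulated cell death genes gave 13 higher and 4 lower of 25 tested, the same adjusted over the list alone, against 16 higher and 1 lower with library totals (camera adjusted p = 0.0218, and adjusted p = 0.198 with an estimated correlation; 0.0821 on log2(FPKM + 1), where the mean log2 change relative to all tested genes was 0.47 against 0.57, adjusted p over the alternatives 1.03e-05 to 0.298), including Ripk3 (2.51 ± 0.25) of necroptosis and Nlrp3 (2.56 ± 0.28) of the inflammasome. The log2 fold change of Nlrp3 went as low as 0.85 over the alternatives, of which 19 tested it, so the size of its rise is uncertain. Immediate early genes gave 16 higher and 1 lower of 24 tested, the same adjusted over the list alone (camera adjusted p = 0.000131, and adjusted p = 0.354 with an estimated correlation), with Socs3 at 3.86 ± 0.19. Ribosomal protein genes gave 50 higher and 1 lower of 81 tested, 57 and 1 adjusted over the list alone, and 79 higher with library totals (camera adjusted p = 1.2e-05, and adjusted p = 0.629 with an estimated correlation).

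In the main camera test, other stress and metabolic lists were not called. The integrated stress response gave 11 higher and 3 lower of 19 tested, 12 and 3 adjusted over the list alone (camera adjusted p = 0.127; 0.032 without control replicate 3, range over the alternatives 0.032 to 0.688), with Mthfd2 at 1.65 ± 0.22 and Shmt2 at -1.44 ± 0.20. Glycolysis genes gave 2 higher and 6 lower of 19 tested, the same adjusted over the list alone, against 5 higher and 2 lower with library totals, 13 lower with a GC offset and 12 lower without both libraries numbered 3 (camera adjusted p = 0.278; 0.0384 without Wnt1 replicate 3, range over the alternatives 0.0384 to 0.862). Their median was -0.30 and their mean 0.02, with hexokinase Hk2 rising by 4.15 ± 0.23. Cholesterol synthesis genes gave 7 higher and 4 lower of 21 tested, 7 and 5 adjusted over the list alone, against 13 higher and 1 lower with library totals (camera adjusted p = 0.784), with Cyp51, of sterol synthesis, at -1.72 ± 0.14. NRF2 targets gave 7 higher and 7 lower of 22 tested, 8 and 7 adjusted over the list alone, against 12 higher and 3 lower with library totals (camera adjusted p = 0.922; the test's direction was lower although the median was 0.09), with Gsta1 at 5.31 ± 0.53 and Me1 at -1.72 ± 0.13. Hypoxia response genes gave 0 higher and 4 lower of 15 tested, the same adjusted over the list alone, against 6 higher and 2 lower with library totals (camera adjusted p = 0.217), with Car9 at -2.70 ± 0.21. Circadian clock genes gave 2 higher and 6 lower of 18 tested, the same adjusted over the list alone, against 5 higher and 4 lower with library totals (camera adjusted p = 0.233). Unfolded protein and heat shock genes gave 4 higher and 5 lower of 29 tested, the same adjusted over the list alone, against 13 higher and 2 lower with library totals, and 9 higher and 8 lower without both libraries numbered 3 (camera adjusted p = 0.828; direction lower, median 0.10). X- and Y-linked markers gave 0 higher and 0 lower of 4 tested, the same adjusted over the list alone, against 1 higher with library totals and 4 higher without both libraries numbered 3 (camera adjusted p = 0.768). The list of nuclear and non-polyadenylated RNA held 3 tested histone genes, all lower (camera adjusted p = 0.0215, and adjusted p = 0.354 with an estimated correlation).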

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

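Choices named as added were made after seeing the data, and so were their tests. Against 5936 calls, voom with quality weights gave 9042 genes (4430 lower), 1 surrogate variable 9248 (4425 lower), and, as added choices, leaving out control replicate 3 and Wnt1 replicate 3 9096 (4432 lower), a covariate for those libraries 9115 (4270 lower) and a GC offset 4065 lower of 7753. Limma gave 5144 higher, 1238 lower and 2183 at least 2-fold on log2(FPKM + 1), 5139 higher and 1234 lower on log2(FPKM + 0.1), and 5949 higher, 1273 lower and 2192 at least 2-fold with no filter. Library totals, an added choice, gave 6348 higher and 1288 lower, and FPKM likewise has no factor for composition. Leaving out 1 library gave 4518 to 8142 genes changed, 2681 to 4165 higher, 1797 to 3977 lower, 2940 to 3821 at least 2-fold, 32 to 34 lists, and 0 to 1 read for the Wnt1 transcript in the Wnt1 group. The calls were 8142 without Wnt1 replicate 3 and 1797 lower without control replicate 2. No gene called by TMM and edgeR was called in the opposite direction in any of the 21 settings, but 106 to 107 changed sign on FPKM and 98 with library totals, where 74.1% to 76.3% of the calls tested were kept, and leaving out 1 library kept 74.8% to 98.1%. Of 150 genes followed across settings 141 kept their direction and their side of the threshold in the settings that tested them, which for some genes were fewer. With an estimated correlation, camera called 0 lists (smallest adjusted p 0.109, 12 at an unadjusted p under 0.05), and also 0 with the added covariate (0.287), while fry called 39. Fewer degrees of freedom alone raise the p-values of that camera test. Ctnnb1, never called on counts with TMM, was at -0.0048 by voom, -0.020 to 0.14 when leaving out 1 library, and -0.013 without both libraries numbered 3. The other reversals were in the direction of the test, for lists that were not called. Values are their mean log2 change relative to all tested genes (for fry, the mean itself), whose sign need not follow the test. NRF2 targets were at 0.33 by fry and 0.054 to 0.14 when leaving out 1 library. Unfolded protein genes were at 0.077 by fry, 0.082 on log2(FPKM + 1), -0.085 without both libraries numbered 3 and -0.25 to -0.078 when leaving out 1 library. Urothelium was at 0.096 on log2(FPKM + 1) and -0.45 to 0.61 when leaving out 1 library, X- and Y-linked markers at -0.016 to 0.64, and cholesterol synthesis at -0.18 with 1 called member left out. Fry does not compare a list with other genes, so its direction can differ from that of camera on the same data. The cause of the reversals was not tested in these cases. No paired analysis was possible because the replicate numbers follow the order of the records, and the titles of the groups share fewer than 2 numbers.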

Other observations

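All tests in this part, other than those on splits of the libraries, were chosen after the results they concern had been seen. The table's own KEGG terms gave 155 of 334 terms called by camera with the preset correlation, and 0 with an estimated correlation (smallest adjusted p 0.317). Here too, fewer degrees of freedom alone raise the p-values with an estimated correlation. Breakdown of valine, leucine and isoleucine stood first among the lower terms, with 40 of 51 tested genes called lower and 3 higher (camera adjusted p = 4.18e-16, and adjusted p = 0.317 with an estimated correlation). Its genes outside the fixed lists included Abat (-2.26 ± 0.15), Oxct1 (-2.06 ± 0.16), which uses ketone bodies, and Mccc1 (-1.77 ± 0.15), of leucine breakdown. Beta-alanine metabolism had 21 of 29 lower and 3 higher (camera adjusted p = 1.04e-12, and adjusted p = 0.317 with an estimated correlation), with the pyrimidine-degrading enzyme Dpys at -3.79 ± 0.21 and carnosinase Cndp1 at -2.70 ± 0.13. Tryptophan metabolism had 27 of 39 lower and 7 higher (camera adjusted p = 3.16e-09, and adjusted p = 0.317 with an estimated correlation), with Aadat at -2.82 ± 0.17 and Kmo at -1.70 ± 0.14, both of the kynurenine route. Glycine, serine and threonine metabolism had 28 of 38 lower and 3 higher (camera adjusted p = 3.51e-10, and adjusted p = 0.363 with an estimated correlation), with cystathionine beta-synthase, Cbs, at -2.78 ± 0.18. Among higher terms, cytokine-receptor interaction had 120 of 181 genes higher and 7 lower (camera adjusted p = 2.85e-17, and adjusted p = 0.317 with an estimated correlation), with the IL-1 receptor antagonist Il1rn at 6.20 ± 0.29 and Ccl9 at 4.61 ± 0.25. Osteoclast differentiation had 70 of 115 higher and 8 lower (camera adjusted p = 1.81e-11, and adjusted p = 0.317 with an estimated correlation), with the myeloid receptor Trem2 at 5.69 ± 0.32 and Fcgr3 at 3.50 ± 0.16. These genes were chosen after their values were seen. In the same libraries proximal tubule markers had a median of -1.83 (26 of 27 lower) and macrophage markers one of 2.99 (18 of 19 higher), so the terms are not separated from those cell types.

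The split by group called 5936 genes (3239 higher, 2697 lower, 3292 at least 2-fold), 1 of 10 splits with as many, and the highest other split called 0 in each case by edgeR, with 5 to 1136 genes at an unadjusted p under 0.05. For lists, 3 of the 10 splits called at least the 33 of the real one, and the highest other called 35. With 10 splits no share can fall under 0.05. Each of the other splits puts 2 libraries of a group with 1 of the other. Part of the group difference therefore stays in its contrast, and the rest becomes spread within its sides. That spread made 0 gene calls likely in the other splits, so the 0 does not measure false calls. No test separated list calls that come from the remaining group difference from members of a list moving together.

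Control replicate 3 and Wnt1 replicate 3 deviated together from the other libraries of their groups, with a correlation of 0.801 across 12493 genes, which are not independent replicates. Transcript GC content accounted for 38.9% of the variance of the deviation in control and 55.1% in Wnt1. Once that trend was removed the correlation was still 0.654, and 0.771 without a trend on transcript length. Neither trend, taken from each gene's longest annotated transcript, accounted for all of it. The trends were not removed together, and bias that this measure misses would stay, so neither bias is excluded as the whole cause. Red blood cell genes lay 2.56 and 2.11 (log2) above the mean of the other libraries of the group, but control replicate 1 was low, and control replicate 3 lay 0.55 above replicate 2. Without the GC trend the difference from the nearest library of the group was 0.48 in control and 1.53 in Wnt1, so a difference in blood in both groups stays open. Urothelium genes were 0.46 and 1.38 higher in the same libraries, and 0.39 and 0.96 without the GC trend. What else these libraries share, such as a handling day, is not in the labels and stays open, and no biological explanation was tested. Because both groups hold 1 such library, the difference adds spread within groups, and leaving out both gave 9096 calls against 5936. Leaving out Wnt1 replicate 3 alone gave 8142 calls and control replicate 3 alone 4903, so the gain went mostly with the Wnt1 library.

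Proximal tubule genes were lower and immune genes higher in the same libraries, and a smaller share of tubule cells alone would raise the markers of all other cells alike. The median of endothelial members lay -3.51 (log2) from that of macrophage members, with quartiles of -0.74 to -0.38 against 2.66 to 3.60, which argues against that as the whole account; a rise of macrophages themselves stays open. Scaling was not the cause of the falls in the proximal tubule, where 25 of 27 genes were lower with library totals, nor was GC content, since 27 were lower with a GC offset. Library totals gave 4 genes lower in intercalated cells, against 8, and 3 in the distal convoluted tubule, against 5, so the falls there are less secure. The Wnt1 plasmid, the only difference the design names, stays among the open explanations, as untested, and so does whether tubule cells were lost beside that rise or expressed less of these genes. Mitophagy genes are less secure, with 17 lower by TMM and 4 by library totals.

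Wnt/beta-catenin targets had 14 genes higher and 3 lower although the Wnt1 transcript had 1 read, and the list was not called with an estimated correlation (adjusted p = 0.119) or on log2(FPKM + 1) (0.0503). The list's estimated correlation was -0.0021, under the preset 0.01, so members moving together do not account for the first of these lost calls. A swap of libraries between the groups would leave a library on the wrong side of the first component, and the groups lay 118.73 score units apart on it with none misplaced; an exchange of all libraries is not excluded. Depth cannot be ruled in or out, since 0 Wnt1 libraries had more than 3 reads, and a plasmid sequence unlike the mouse gene, expression elsewhere in the body or loss by the time of sampling would look alike. Of 13 feedback regulators, 5 were called higher (Nkd2, Tcf7, Nkd1, Apcdd1 and Axin2), and Sp5 (-1.04 ± 0.22) and Notum (-1.32 ± 0.18), chosen after their values were seen, fell. The other 12 targets had 9 higher, so a rise that may follow inflammation and injury cannot be told apart from Wnt signalling here, because the feedback genes go both ways.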
